A study of Mus musculus with 9 samples.

How the data were processed

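The series holds 9 Affymetrix Clariom S mouse arrays hybridised with liver RNA of male ob/ob mice, which lack functional leptin and become obese. Per the labels' protocols, the mice were 6 weeks old when obtained and received vehicle or an extract of Vigna umbellata (VE, rice bean) by gavage for 42 days, at 50 or 100 mg/kg. Each of the 3 groups (vehicle, VE50 and VE100) has 3 arrays. The labels number the arrays within a group as replicates and do not state that each came from a separate animal. Wild-type mice are mentioned in the study's design and were not analysed here. No hybridisation date, scan date or batch is given in the sources used here, so no batch term was fitted.

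The authors' main sheet holds log2 signal per probe set and array, made with the SST-RMA algorithm in Transcriptome Analysis Console 4.0.2, per the series' design text; that step corrects background, normalises between arrays and summarises probes. The deposited value table of the series holds log2 values of the same arrays and also the control probe sets. The submitters' processing notes name RMA and Transcriptome Analysis Console 4, without the RMA variant of that table. The authors' group averages on the log2 scale matched a one-step Tukey biweight average of the 3 arrays within 0.02 for 99.9% of probe sets. The authors also deposited p-values and FDR values of an F-test over conditions, whose conditions are not named. Their filtered table of VE100 against vehicle holds a deposited p-value, an FDR and a signed fold score, which is negative where VE100 was lower. The study's stated criterion was an unadjusted p under 0.05 with a fold above 1.1. Its detection filter needs files not analysed here. Its filter on the area under the curve of positive against negative controls has a threshold of 0.7. Computed here from the deposited value table, that area ran from 0.772 to 0.824 over the 9 arrays, though the study's own values may differ.

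All 22206 probe sets of the signal sheet were tested. Of these, 21340 carry 1 gene symbol, 836 carry several, 3 carry none and 27 carry a symbol that spreadsheet software had turned into a date. Gene names are those of the authors' sheet; 20555 of 21130 distinct single symbols were found in a reference annotation of mouse genes, used for names alone. No coordinates are given, since no genome build is named in the sources used here. Signal ran from 1.92 to 19.93 on the log2 scale. Between 14.3% (vehicle 3) and 20.2% (vehicle 1) of the probe sets lay above the 95th percentile of the negative control probe sets of their array. The number of arrays limits the precision of every value.

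A linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Contrasts were VE50 against vehicle, VE100 against vehicle, VE100 against VE50, and the mean of both doses against vehicle; a moderated F-test covered the 3 groups. P-values are two-sided and were adjusted with the Benjamini-Hochberg method over all probe sets, with 0.05 as the threshold. Beside the adjusted counts stand counts at the study's criterion. The difference between doses was tested by its own contrast. Errors beside a log2 difference are standard errors from the limma fit, with 3 arrays per group; group values are means with SD.

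Before the data were examined, 49 gene lists were fixed, for metabolic, stress and immune pathways and for markers of liver and other cell types; 883 of their 935 members were measured. Each symbol entered with the probe set of highest mean signal. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 49 lists within a contrast. Camera with an estimated correlation and fry were run beside it, fry both for a shift in 1 direction and for changes in either direction. Fry asks whether members change at all, not whether they change more than other genes. Its test in either direction was not repeated under the alternatives. Named genes followed a rule fixed in advance. For each comparison with vehicle, it takes the 10 highest and 10 lowest differences among single-symbol probe sets past the adjusted threshold whose arrays do not overlap between groups. Places left open go to those past the study's criterion, and for VE100 against VE50 the rule takes 5 and 5. For genes taken this way, arrays that do not overlap are a condition of the choice and no separate evidence. It adds the 4 members with the smallest p in the direction of each list past camera and 1 against it, and up to 2 members of every other list. Predicted and clone-named genes are counted but not named. Genes named outside this rule are stated to have been chosen after their values were seen.

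The fits were tested on simulated data with the real spread of each probe set, in which 200 of 22206 probe sets were changed, 50 per size. For VE100 against vehicle, limma recovered 0 of 50 changes of 0.5 on the log2 scale, 9 of 50 of 1, 30 of 50 of 2 and 44 of 50 of 3, with 4 false calls among 22006 unchanged probe sets. For both doses against vehicle it recovered 0, 7, 44 and 49 of 50, with 8 false calls. These simulations took genes as independent, with 1 spread per probe set for all arrays. They thus cannot give the rates for the real arrays, among which vehicle 3 stood apart. A simulated shift of -0.60 in the 22 measured lipogenesis genes of VE100, with genes independent of each other, was recovered in 20 of 20 sets by camera at the preset correlation, in 12 by camera with an estimated correlation and in 13 by fry.

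Agreement between the doses was set against 100 simulations of unchanged groups that share 3 simulated vehicle arrays. The simulations took genes as independent, with 1 spread per probe set for all arrays. The 3 real vehicle arrays are too few to be split. Alternatives were the replicate number as a block, filters on low signal, other scalings, the deposited value table, array weights, other limma settings, a fold above 1.5, fits on the arrays of 2 groups alone, and leaving out each array in turn. After the data had been seen, 2 measures of the control probe sets were added as covariates, and a list of splicing regulators was added. An alternative value of the correlation between doses counts as moved where it lies further from the reported value than 1 SD of the leave-one-out values. Small groups of arrays were compared by exact permutation tests, which cannot go below p = 0.1 for 3 against 3 arrays or p = 0.0119 for 3 against 6. Figures were drawn with matplotlib 3.10.9.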

Results

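Liver expression was measured in 3 groups of 3 arrays each from obese ob/ob mice given vehicle, 50 mg/kg or 100 mg/kg of a Vigna umbellata extract (VE50, VE100) for 42 days. The comparisons ask how each dose differs from vehicle, whether the doses differ from each other, and what both have in common. The 3 arrays per group limit the precision of each value. Genome-wide signal correlated between 0.974 and 0.990 across genes among 8 of the arrays, and between 0.948 and 0.967 for vehicle 3 with the others. Vehicle 3 also carried far higher signal of inducible acute phase genes, chosen after their values were seen: Saa2 reached 18.75 on the log2 scale, against 7.84 to 11.81 on the other 8 arrays, and Saa1 15.76 against 5.57 to 9.75. Counts without this array therefore stand beside each comparison with vehicle.

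At 50 mg/kg, several genes known to respond to glucocorticoid hormones had higher signal than in vehicle livers. Fkbp5, a chaperone of the glucocorticoid receptor, had a mean signal of 12.81 ± 0.48 (SD, n = 3) on the log2 scale in VE50 and 11.24 ± 0.32 in vehicle, a log2 difference of 1.57 ± 0.43 (SE). Zbtb16, a transcription factor gene, lay higher by 1.64 ± 0.49, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, by 1.16 ± 0.39 (1.01 without VE50 3, no longer past the study's criterion). Of the acute phase genes, several had lower signal, with Saa4, a serum amyloid A apolipoprotein, at -1.51 ± 0.45 and Lbp, the lipopolysaccharide binding protein, at -1.24 ± 0.36. For each of these 5 genes, all 3 VE50 arrays lay on the same side of all 3 vehicle arrays, and the adjusted p from limma was 0.794. The naming rule asks this separation of the genes with the largest differences.

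As groups, both lists passed camera for VE50 at the preset correlation. The glucocorticoid list shifted higher, with a median log2 difference of 0.32 over 15 measured genes, 10 of them above 0 and 4 past the study's criterion (adjusted p = 0.0451). The acute phase list shifted lower, with a median of -0.34 over 21 genes, 19 of them below 0 and 3 past the criterion (adjusted p = 0.0451). Both had an adjusted p = 0.973 with an estimated correlation, and fry called 0 lists for a shift in 1 direction or in either. No member of either list passed the adjusted threshold over all genes, and 0 passed when adjusted over the list alone. Members that went the other way were Il6ra, a subunit of the interleukin 6 receptor, at 0.79 ± 0.46 (0.48 without vehicle 3, 0.52 without VE50 3), and the metallothionein gene Mt2 at -2.20 ± 1.41; neither passed the criterion, though Mt2 did without VE50 3 (-3.55). Without vehicle 3 the acute phase median turned to 0.08 (adjusted p = 0.815), and the glucocorticoid list no longer passed (adjusted p = 0.395). The acute phase list also lost its call without VE50 1 (adjusted p = 0.111), VE50 2 (0.0669), VE50 3 (0.0678) or VE100 1 (0.0528). The glucocorticoid list lost its call without vehicle 2 (0.0659), VE50 1 (0.111), VE50 3 (0.206) or VE100 1 (0.0528). Both lists also lost their call with the replicate number as a block (adjusted p = 0.0596 for both), without probe sets of lowest signal (0.0813 for glucocorticoid, 0.0621 for acute phase), with median-centred arrays (0.0677, 0.0668), in the deposited value table (0.0682 for both) and with array weights (0.180, 0.682).

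Among the named genes past the criterion whose arrays did not overlap, Alas1, the rate-limiting enzyme of heme synthesis, had the highest difference for VE50, 2.11 ± 0.66, and lay at 1.20 without vehicle 3. Next came Lpin1, a phosphatidate phosphatase of triglyceride synthesis, at 2.06 ± 0.57, and G0s2, an inhibitor of adipose triglyceride lipase, at 2.05 ± 0.49. Onecut1, a hepatocyte transcription factor gene, lay higher by 2.05 ± 0.64, and Por, the electron donor of microsomal cytochrome P450 enzymes, by 1.52 ± 0.52 (0.79 without vehicle 3). Wsb1 (1.70 ± 0.36) and Arhgef26 (1.62 ± 0.33) were also higher on every VE50 array. The authors' vehicle average of Wsb1 was 4.81, below the median signal of the vehicle arrays (5.07 to 5.28). The clock gene Nr1d1, which encodes the nuclear receptor REV-ERB alpha, was lowest of the same set at -1.58 ± 0.30. Also low were Abhd4 (-1.42 ± 0.32), the transcriptional repressor gene Bcl6 (-1.37 ± 0.42) and Ccni (-1.37 ± 0.37).

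Across all genes, limma called 0 of 22206 probe sets for VE50, with a smallest adjusted p of 0.794. At an unadjusted p under 0.05 there were 1358, where chance alone gives 1110.3, and the same 1358 passed the study's criterion, 736 higher and 622 lower. Without vehicle 3, limma called 10 probe sets (1 higher, 9 lower), 1 of them among the 1358, and 2991 passed the criterion, now with more lower (1669) than higher (1322). Arrays did not overlap for 10.9% of probe sets, where chance gives 10%.

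At 100 mg/kg, several glucocorticoid-responsive genes had higher signal than in vehicle, and several genes of fat synthesis and antioxidant defence had lower signal. Fkbp5 lay higher than in vehicle by 2.36 ± 0.43 (SE) on the log2 scale, a fold of 5.13, and Zbtb16 by 2.54 ± 0.49, a fold of 5.80. Igfbp1, a hepatic binding protein of insulin-like growth factors that insulin represses, had the highest difference of the named genes past the criterion whose arrays did not overlap, 2.76 ± 0.51, a fold of 6.77. Pklr, the liver pyruvate kinase, lay lower at -1.09 ± 0.29, and Hmox1, heme oxygenase 1, at -1.38 ± 0.34. All 3 VE100 arrays lay beyond all 3 vehicle arrays for these 5 genes, whose adjusted p from limma ran from 0.294 to 0.343.

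For VE100, 5 lists passed camera at the preset correlation, and all 5 had an adjusted p = 0.972 with an estimated correlation. Fry called 0 lists for a shift in 1 direction. Its test of changes in either direction passed for the glucocorticoid list (adjusted p = 0.00844), glycolysis and glycogen genes (8.07e-06) and circadian genes (0.0237). That test does not compare a list with other genes and was not repeated without single arrays. The lipogenesis list shifted lower (median -0.74, 16 of 22 measured genes below 0, adjusted p = 0.0229), with 7 members past the criterion lower and 1 higher. Among them were Acaca (-1.26 ± 0.40) and Acly (-1.29 ± 0.44), which supply malonyl-CoA and acetyl-CoA for fatty acid synthesis, and Agpat2 (-1.08 ± 0.33) of triglyceride synthesis; Lpin1 lay the other way, at a fold of 2.82. The list of NRF2 and glutathione genes shifted lower (median -0.49, 18 of 23 below 0, adjusted p = 0.0229), with Gclc (-1.26 ± 0.40) and Gclm (-0.66 ± 0.26), the subunits of the enzyme that limits glutathione synthesis, while Nqo1 lay at 0.76 ± 0.40 and did not pass the criterion (0.30 without VE100 1; 1.10 without VE100 3, where it passed). The macrophage list shifted lower (median -0.58, 18 of 22 below 0, adjusted p = 0.0229). It includes Adgre1, a macrophage surface receptor gene (-1.05 ± 0.28), Cd5l of Kupffer cells (-2.13 ± 0.64) and Mpeg1 (-1.18 ± 0.42), and the hemoglobin scavenger receptor gene Cd163 lay the other way at 1.22 ± 0.31. The interferon list shifted lower (median -0.23, 22 of 26 below 0, adjusted p = 0.0229), with Irf7 at -0.88 ± 0.32 and Ifit3 at -1.12 ± 0.46. The glucocorticoid list shifted higher (median 0.61, 9 of 15 above 0, adjusted p = 0.0258), and its member Lcn2, itself an acute phase gene, lay at -2.65 ± 1.46 and did not pass the criterion; it lay at -0.92 without vehicle 3, -1.40 without VE100 3 and -3.65 without vehicle 2, where it passed. Over all genes 0 members passed the adjusted threshold; adjusted over the list alone, 4 glucocorticoid and 2 macrophage genes passed and 0 of the other 3 lists.

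**Figure D1:**
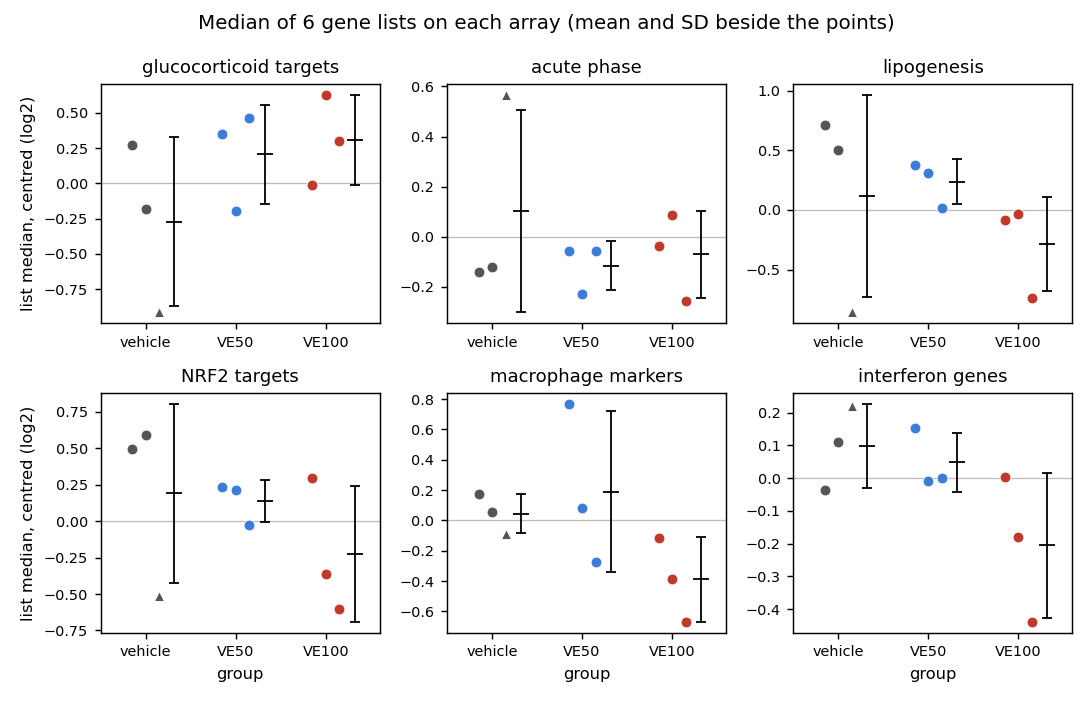
Median of 6 gene lists on each array (log2, after centring each gene on its mean over the 9 arrays), by group; bars give the mean and SD of 3 arrays, and the triangle is vehicle 3. Vehicle 3 lies at 0.57 for the acute phase list and -0.86 for lipogenesis, apart from the other vehicle arrays, and VE100 3 lies lowest of the VE100 arrays for lipogenesis at -0.74.

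These lists rested on single arrays. All 5 lost their call without VE100 3, with adjusted p = 0.262 for lipogenesis and for macrophages, 0.572 for NRF2 genes, 0.152 for interferon genes and 0.123 for the glucocorticoid list. Without vehicle 3 the glucocorticoid list (adjusted p = 0.287) and the interferon list (0.119) no longer passed, whereas lipogenesis had a median of -1.12 (adjusted p = 1.90e-07), NRF2 genes -0.82 (1.11e-05) and macrophages -0.49 (0.0288). Lipogenesis and NRF2 genes lost their call without vehicle 1 (adjusted p = 0.463 and 0.153) or vehicle 2 (0.249 and 0.386). Without VE100 2, the NRF2 list (0.0902) and the glucocorticoid list (0.127) lost theirs. The lipogenesis median also turned higher, to 0.13 and 0.25, when either of 2 control-probe measures entered the fit as a covariate, a step chosen after the data were seen. Of the members named above, 6 no longer passed the criterion without VE100 3: Acly (-0.90), Gclm (-0.61), Irf7 (-0.67), Ifit3 (-0.80), Mpeg1 (-0.84) and Lpin1 (1.12). Lpin1 also lost it without vehicle 3 (1.06), vehicle 2 or VE100 2 (1.20), and Ifit3 without vehicle 3 (-0.63) or VE100 2 (-1.11). Gclm lost it without vehicle 1 (-0.62), vehicle 2 (-0.49) or VE100 1 (-0.53), Irf7 without vehicle 1 (-0.61) or VE100 2 (-0.81), and Mpeg1 without vehicle 1 (-0.96).

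Of single genes, those nearest the adjusted threshold for VE100 were Eef1b2, a translation elongation factor subunit, at -1.95 ± 0.23 and Nr1d1 at -2.43 ± 0.30, each with an adjusted p of 0.0868 and with all 3 arrays below vehicle. Eef1b2 signal was 15.42 ± 0.18 (SD, n = 3) in vehicle, 14.66 ± 0.37 in VE50 and 13.47 ± 0.10 in VE100. Por (2.27 ± 0.52), G0s2 (2.17 ± 0.49), Il6ra (2.13 ± 0.46), Erdr1 (2.08 ± 0.34) and Rsrp1 (1.94 ± 0.37) were among the highest. Among the lowest were Spi1, which encodes the myeloid transcription factor PU.1 (-2.40 ± 0.57), the tumour necrosis factor receptor gene Tnfrsf1a (-2.22 ± 0.69), and the tubulin genes Tuba1b (-2.17 ± 0.50) and Tubb4b (-2.08 ± 0.42). With the hybridization controls as a covariate, chosen after the data were seen, Spi1 lay at -0.97 and Tnfrsf1a at -0.58, neither past the criterion, which 62 of 126 named values lost there. Ly6d, at -2.51 ± 0.86, was the lowest of the named genes past the criterion whose arrays did not overlap; without VE100 3 it lay at -1.59, and it passed the criterion under 18 of 20 alternatives.

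**Figure D2:**
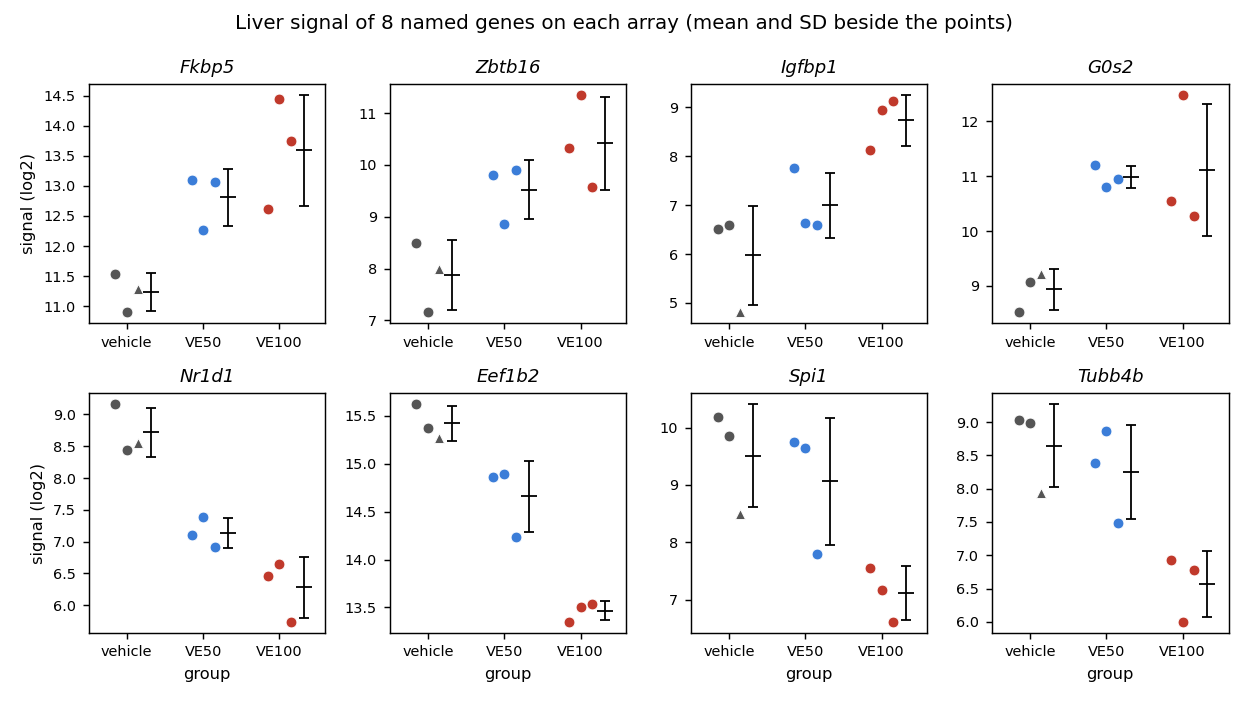
Signal (log2) of 8 named genes on each array, by group; bars give the mean and SD of 3 arrays, and the triangle is vehicle 3. Nr1d1 averaged 8.72 in vehicle, 7.13 in VE50 and 6.28 in VE100, and Spi1 and Tubb4b were low on all 3 VE100 arrays.

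Across all genes, limma called 0 of 22206 probe sets for VE100, with a smallest adjusted p of 0.0868. An unadjusted p under 0.05 was reached by 2105, where chance gives 1110.3, and all 2105 passed the study's criterion, 1135 higher and 970 lower. Without vehicle 3, limma called 434 probe sets, 88 higher, of which 214 were among the 2105, and 3688 passed the criterion, now with more lower (2136) than higher (1552). Nr1d1 (-2.52, adjusted p = 0.00794), Eef1b2 (-2.03, 0.00775), Tuba1b (-2.82, 0.00562), Spi1 (-2.91, 0.0202), Igfbp1 (2.18, 0.0202), Fkbp5 (2.38, 0.0277) and Zbtb16 (2.59, 0.0310) were among those 434. That fit sets 2 vehicle arrays against 3. On vehicle 1 and vehicle 2 the negative less the positive control median was -3.88 and -3.79, against -3.53 to -3.12 on the treated arrays. Hybridization controls averaged 10.84 and 10.73 there, against 10.93 to 11.44 on the treated arrays. Without vehicle 3, treatment thus cannot be told apart from an array-level difference, at either dose. The authors' filtered table holds 1815 probe sets (995 higher, 820 lower) with a smallest deposited FDR of 0.210; 1689 of them passed the criterion here, and all 1815 had the same direction. Arrays did not overlap for 13.6% of probe sets, where chance gives 10%.

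**Figure D3:**
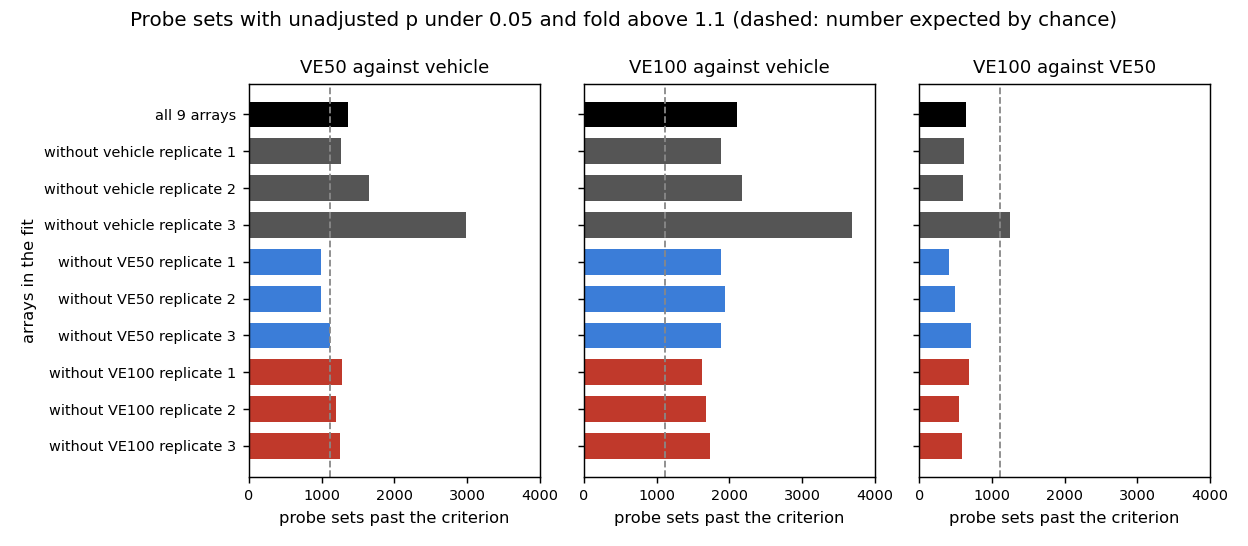
Number of probe sets past the study's criterion with all 9 arrays and without each array, for 3 comparisons; the dashed line is the 1110.3 expected by chance. Leaving out vehicle 3 gives the highest count in each, 2991 for VE50, 3688 for VE100 and 1247 for the doses against each other.

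Between the doses, lists of macrophage, fat synthesis and amino acid catabolism genes passed camera at the preset correlation. None of these 3 passed with an estimated correlation, at an adjusted p = 0.742 for macrophages and 0.957 for the other lists. The macrophage list lay lower in VE100 (median -0.46, 21 of 22 measured genes below 0), though its medians per array overlapped, at 0.77, 0.08 and -0.28 in VE50 and -0.11, -0.39 and -0.67 in VE100. Among its members were Spic, a transcription factor gene of red pulp and Kupffer-type macrophages, at -1.21 ± 0.34 (SE), Cd68 at -1.10 ± 0.41 and Cd5l at -1.61 ± 0.64. The lipogenesis list lay lower (median -0.60, 21 of 22 below 0), with Pklr at -1.01 ± 0.29 and Aacs, a ketone body-using enzyme of lipid synthesis, at -1.09 ± 0.41. The criterion was lost by Cd5l without VE100 3 (-1.03), VE50 1 (-1.06) or VE50 2 (-1.56), and by Aacs without VE100 3 (-0.82), VE50 1 (-1.10) or VE50 2 (-0.94). Cd68 lost it without VE50 1 (-0.74), VE50 2 (-1.07), VE100 1 (-1.01) or VE100 3 (-1.05). The list of urea cycle and amino acid catabolism genes lay higher (median 0.33, 21 of 22 above 0), but 0 of its members passed the criterion, among them Asl, argininosuccinate lyase, at 0.76 ± 0.53 (0.21 without VE100 3; 1.37 without VE100 1, where it passed). Its median per array overlapped between the doses, at -0.53, -0.25 and 0.25 in VE50 and -0.50, 0.24 and 0.62 in VE100, and without VE100 3 the list did not pass (adjusted p = 0.933).

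In all, 10 lists passed camera between the doses at the preset correlation, 7 lower in VE100 and 3 higher. With an estimated correlation, 0 passed: the adjusted p was 0.742 for macrophage, interferon and muscle lists and 0.957 for the other 7, and fry called 0. At the preset correlation, adjusted p = 3.97e-06 for macrophages, 1.25e-05 for lipogenesis and 0.00326 for the urea list. Also lower were interferon genes (median -0.26, 22 of 26 below 0, adjusted p = 1.85e-04; Tap1 -0.68 ± 0.22), NRF2 genes (median -0.34, 21 of 23, 0.00374), cell cycle genes (median -0.22, 21 of 29, 0.00374; Mcm6 -0.91 ± 0.38, past the criterion under 14 of 20 alternatives, from -1.39 without VE100 1 to -0.63 without VE100 3), ribosomal protein genes (median -0.26, 26 of 30, 0.00598) and cholesterol synthesis genes (median -0.22, 20 of 24, 0.00838; Fdps -0.93 ± 0.41, -0.61 without VE100 3, and past the criterion under 10 of 20 alternatives). Markers of pericentral hepatocytes (median 0.23, 11 of 14 above 0) and of striated muscle (median 0.17, 11 of 14) were higher, each with an adjusted p = 0.0490. No member passed the adjusted threshold over all genes, and 0 passed when adjusted over the list alone. Without VE50 1, 3 lists passed (macrophage, lipogenesis and interferon), and without VE100 3, 4 passed. Those lost without VE100 3 were interferon (adjusted p = 0.0531), urea cycle (0.933), NRF2 (0.725), cell cycle (0.133), cholesterol synthesis (0.206) and pericentral genes (0.745). The NRF2 (0.0602) and cell cycle (0.0680) lists also lost their call without VE100 2, and ribosomal genes without VE100 1 (0.503). Muscle markers lost theirs without vehicle 3 (0.0560), VE50 3 (0.240), VE100 1 (0.319) or VE100 2 (0.0602). Pericentral markers lost theirs without vehicle 1 (0.0594), vehicle 2 (0.0564), vehicle 3 (0.0724) or VE50 2 (0.117).

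Of the named genes past the criterion whose arrays did not overlap, those with the highest differences between the doses included Igfbp1 (1.74 ± 0.51) and the glycosyltransferase-like gene Glt1d1 (1.39 ± 0.38). The lowest were Spi1 (-1.96 ± 0.57), Phlda1 (-1.74 ± 0.47), Tubb4b (-1.67 ± 0.42), the activin subunit gene Inhbe (-1.55 ± 0.65) and the centromere gene Cenpq (-1.25 ± 0.41). Inhbe lost the criterion without VE50 1 (-1.66), VE50 2 (-1.34), VE50 3 (-1.66), VE100 1 (-1.42) or VE100 3 (-1.16), and Cenpq without VE100 2 (-0.87). All 3 VE100 arrays lay beyond all 3 VE50 arrays for each of these 7, and the adjusted p from limma was 0.9997. Across all genes limma called 0 probe sets, and 647 had an unadjusted p under 0.05 and passed the criterion (330 higher, 317 lower), fewer than the 1110.3 of chance. Without vehicle 3, which enters this contrast through the shared spread, 1247 passed (564 higher, 683 lower), and without VE50 1, 413. Arrays did not overlap for 2221 of 22206 probe sets, where chance gives 10%.

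Taking both doses together, Nr1d1 was the gene nearest the adjusted threshold, lower at -2.01 ± 0.26 (SE) on all 6 treated arrays (adjusted p = 0.268). Ppp1r3b, a glycogen-targeting phosphatase subunit, lay higher at 1.24 ± 0.21 and Gys2, the liver glycogen synthase, at 1.01 ± 0.21, while their list of glycolysis and glycogen genes had 11 of 22 members above 0 and did not pass camera (median 0.03, adjusted p = 0.610). Its members went both ways: fry's test of changes in either direction gave an adjusted p = 4.23e-06, and 4 members passed when adjusted over the list alone. Neither result compares the list with other genes, and the fry test was not repeated without single arrays. Genes of insulin signalling went both ways: Irs2, the insulin receptor substrate, lay at -1.02 ± 0.23, Igfbp1 at 1.89 ± 0.44 and the transcription factor gene Foxo1 at 1.04 ± 0.26. For each of these 6 genes the 6 treated arrays lay on one side of the 3 vehicle arrays, and the adjusted p of the last 5 was 0.328 to 0.338.

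The genes with the highest differences for both doses, of the named genes past the criterion whose arrays did not overlap, were G0s2 (2.11 ± 0.43), Zbtb16 (2.09 ± 0.42), Fkbp5 (1.97 ± 0.37) and Por (1.90 ± 0.45, and 1.16 without vehicle 3). The lowest after Nr1d1 were Arrdc3 (-1.73 ± 0.56), Mmd2 (-1.68 ± 0.44, and -1.03 without vehicle 1), Isoc1 (-1.60 ± 0.37) and Saa4 (-1.55 ± 0.39). Of macrophage genes, Cd163 lay at 1.25 ± 0.27 and Adgre1 at -0.86 ± 0.24 (-0.55 without vehicle 3), and the list did not pass camera (median -0.21, 14 of 22 below 0, adjusted p = 0.431). The clock repressor gene Cry1 lay at 0.81 ± 0.20 and the glutathione peroxidase gene Gpx1 at -0.72 ± 0.23 (-0.58 without vehicle 2, no longer past the criterion). The respiratory chain genes Ndufb3 and Cox7b lay at 0.62 ± 0.18 and 0.77 ± 0.24. Cox7b lay at 0.53 without vehicle 1, no longer past the criterion, and at 1.01 without vehicle 3 (adjusted p from limma = 0.0483). None of the 49 lists passed camera at the preset correlation; the glucocorticoid list (median 0.28, 10 of 15 above 0) had an adjusted p = 0.0577 and the acute phase list (median -0.42, 17 of 21 below 0) 0.0657. Their adjusted p = 0.998 with an estimated correlation; fry called 0 lists for a shift in 1 direction, and the glucocorticoid list for changes in either (0.0228). In each of these 2 lists, 4 genes passed when adjusted over the list alone and 0 over all genes. Without single arrays the count of lists was 4 (vehicle 1), 3 (vehicle 2), 7 (vehicle 3), 1 (VE50 2) and 4 (VE100 1). Without vehicle 3 the acute phase median was -0.03 and its test turned higher (adjusted p = 0.861).

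Across all genes limma called 0 probe sets for both doses, with a smallest adjusted p of 0.268, and 2108 had an unadjusted p under 0.05 and passed the criterion (1110 higher, 998 lower). Without vehicle 3, limma called 477, of which 109 were higher and 198 were among the 2108, and 3765 passed the criterion, now with more lower (2137) than higher (1628). Nr1d1 (-2.09, adjusted p = 0.0124), Ccni (-1.91, 0.0143), Abhd4 (-1.70, 0.0144), Ppp1r3b (1.18, 0.0302) and Gys2 (1.13, 0.0324) were among the 477. Here too, treatment cannot be told apart from the array-level difference of the remaining vehicle arrays given for VE100. Arrays did not overlap for 4.71% of probe sets, where chance gives 2.38%. The F-test over the 3 groups called 0 probe sets (smallest adjusted p 0.295, 1452 at an unadjusted p under 0.05), and 107 without vehicle 3.

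The differences of VE50 and of VE100 from vehicle correlated at r = 0.725 across probe sets, which are not independent replicates. Simulated unchanged groups that share 3 simulated vehicle arrays gave a mean r of 0.502 and at most 0.523 in 100 simulations. The covariance was 0.111 against a simulated 0.0548. Both differences had the same sign for 75.3% of probe sets, against 66.7% in the simulations. In both comparisons 686 probe sets passed the criterion in the same direction (385 higher, 301 lower) and 0 in opposite directions, against 249.7 in the simulations and 64.8 for independent lists. Part or all of the excess may come from the shared vehicle arrays, which are too few to split. The correlation was 0.804 without vehicle 3, where simulations with 2 vehicle arrays gave at most 0.612. It was 0.620 without VE50 3, where they gave at most 0.470. Every simulation took genes as independent and gave each probe set 1 spread for all arrays, whereas vehicle 3 stood apart (array weight 0.215). The simulated values therefore cannot show how far the agreement exceeds chance.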

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

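The tests of an acute phase response in vehicle 3 and of the deposited F-test were chosen after values had been seen.

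Between VE100 and VE50, 10 gene lists differed by camera at the preset correlation. With an estimated correlation 0 did (smallest adjusted p = 0.742), fry called 0, and without VE50 1 the preset correlation called 3. Their median log2 differences were -0.60 for lipogenesis, -0.22 for cholesterol synthesis, -0.34 for NRF2 genes, -0.26 for interferon genes, -0.26 for ribosomal proteins, -0.22 for the cell cycle and -0.46 for macrophage markers. The medians were 0.33 for the urea cycle and amino acid catabolism, 0.23 for pericentral markers and 0.17 for muscle markers.

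A signal outside the compared probe sets came from the hybridization controls, bacterial and phage transcripts added to each sample. Their mean on the log2 scale was 10.86 ± 0.14 (SD, n = 3) in vehicle, 11.12 ± 0.18 in VE50 and 11.31 ± 0.14 in VE100, a difference of 0.36 for both doses (exact permutation p = 0.0357). The authors' F-test gave 547 probe sets an FDR under 0.05, and the F-test on the 9 arrays gave 24.7% of them an unadjusted p under 0.05, so samples other than these 9 may have entered it.

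Vehicle 3 stood apart from the other 8 arrays, with Saa2 7.54, Saa1 7.24, Lcn2 5.20 and Itih4 3.75 above the mean of the other vehicle arrays on the log2 scale, and the median of the lipogenesis list at -1.15. Tissue of another organ or more blood is argued against by markers of pancreas, fat, muscle, kidney and gut, and blood: the list medians lay at most 0.51 above the other vehicle arrays, for pancreas. Of its 21 genes 17 were higher (median of the differences 0.61, percentile 99.4 among random lists), but none, the abundant digestive enzymes included, exceeded a signal of 6.20, where the array's median was 5.28. A candidate explanation is an acute phase response in that mouse, with the acute phase list at percentile 99.6 among 10000 random lists, but this does not single it out: ribosome and proteasome lists lay at percentile 100, and lipogenesis, PPAR-alpha and circadian lists at 0. Poor array or RNA quality stays open, because the area under the curve of positive against negative control probe sets was 0.779, the lowest but 1, where the other arrays ran from 0.772 to 0.824; the design names no biological difference within the vehicle group.

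Regrouping the arrays bears on every count. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. For VE50 the real counts and the highest of the other splits were 0 and 0 adjusted calls, 1358 and 2882 probe sets past the criterion, and 2 and 21 lists. For VE100 they were 0 and 0, 2105 and 2780, and 5 and 20. For VE100 against VE50 they were 0 and 0, 647 and 1176, and 10 and 19. The median of the other splits was 983, 1002 and 539 probe sets past the criterion for these 3 comparisons in turn, below the real counts. For lists it was 14, 14 and 9. The list counts of VE50 and VE100 at the preset correlation thus lay below those of typical regroupings. For both doses, chance cannot be excluded for the count past the criterion: 5 of 100 splits, the real one included, had as many probe sets (2108 for the real split, 2731 at most in the others). Some of the others keep part of the real contrast. Splits with vehicle 1 and vehicle 2 beside VE50 2 or VE100 3 gave 2529 and 2203, and splits that kept all 3 vehicle arrays together gave 2073 and 2080. The share is thus no clean measure of chance. A real count of 0 is reached by all 100 of 100 splits by construction, so the splits say nothing on the adjusted calls (0, at most 20 in others), lists (0, at most 22) and F-test calls (0, at most 1). The split of vehicle 1, vehicle 2 and VE50 2 against the rest gave the 20 calls where the real split gave 0, which points to a structure of the samples; splits of vehicle 1 and vehicle 2 with any other treated array gave 0.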

How the results depend on the processing

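The measures of the control probe sets used as covariates and the splicing list were chosen after seeing the data. No named gene changed direction under any alternative run: 2223 values stayed on their side of the study's criterion, 243 no longer passed and 10 newly passed. The naming rule took these genes from the same data by large differences with arrays that do not overlap, or by small p. Where arrays do not overlap, leaving out an array cannot reverse the direction, so the stable direction is no separate evidence. Of the list values, 327 kept their call, 121 lost it, 28 gained it and 5 turned. With each of the 9 arrays left out in turn, adjusted calls ranged from 0 to 10 for VE50, 0 to 434 for VE100, 0 to 477 for both doses and 0 to 107 for the F-test, each highest without vehicle 3; VE100 against VE50 stayed at 0. Counts past the criterion ranged from 987 to 2991, 1619 to 3688, 413 to 1247 and, for both doses, 1782 to 3765. Lists ranged from 0 to 6, 0 to 9, 3 to 11 and 0 to 7, and the correlation from 0.620 to 0.804.

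Without vehicle 3, the acute phase list turned to 0.0767 for VE50, and its test turned at medians of -0.0167 for VE100 and -0.0333 for both doses. Its lowest medians were -0.63 for VE50 without vehicle 2, and -0.70 for VE100 and -0.68 for both doses without vehicle 1. The lipogenesis list in VE100 turned to 0.13 with the control contrast and 0.25 with the hybridization controls as a covariate. The cause of these turns was not tested.

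Array weights, which gave vehicle 3 a weight of 0.215, gave 125 adjusted calls for VE100 and 143 for both doses. They gave 2902, 3743, 1267 and 3867 probe sets past the criterion for VE50, VE100, VE100 against VE50 and both doses, and 4 lists for both doses. The control contrast gave 2799, 3525, 1046 and 3666 past the criterion, 15 lists for VE50 (13 higher), 18 for VE100 (12 higher) and 17 for both doses (13 higher), 1 adjusted call each for VE100, both doses (Igfbp1 in both) and the F-test, and a correlation of 0.879. Hybridization controls gave 1320 past the criterion for VE100, lists of 12 (11 higher), 18 (15 higher), 6 (3 higher) and 17 (15 higher), and a correlation of 0.872; as reported, 1 of 2 and 1 of 5 lists were higher for VE50 and VE100. Dropping probe sets below the median signal left fewer to test, with 744, 1249, 247 and 1248 past the criterion, 1 list for VE50 and 0 for VE100; dropping only those of lowest signal left 0 lists for VE50. Fits on the arrays of 2 groups alone gave 1119 past the criterion for VE100 against VE50. Quantile normalization gave 1 list for VE50 and 1 for both doses, and median centring 0 and 2. The deposited value table gave 0 lists for VE50 and 1 adjusted call for VE100, Nr1d1 (-2.63, adjusted p = 0.0473; 0.00794 to 0.806 over its alternatives). Camera with an estimated correlation and fry's test of a shift in 1 direction gave 0 lists in VE50, VE100 and VE100 against VE50. The cause of these moves was not tested.

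Replicate numbers do not pair the arrays consistently: same-numbered arrays of different groups correlated from -0.237 to 0.208 in their deviations, and 3 of 9 pairs were over 0.1. In both other groups at once, 0 arrays correlated best with their own number, though VE50 3 and VE100 3 correlated best with each other (0.208). With the replicate number as a block, 0 lists passed for VE50, and the counts past the criterion were 1250, 1947, 634 and 1967. Signal over background limits what the arrays show: 14.3% to 20.2% of probe sets lay above nearly all negative controls. Named genes with low authors' averages include Wsb1 (4.81 in vehicle), Cd163 (5.77 in vehicle) and Hao2 (5.02 in VE100).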

Other observations

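The list of splicing regulators with its tests, those with control probe sets as covariates included, the test of Nr1d1 without vehicle 3, and the clock test without vehicle 3 were chosen after values had been seen.

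Transcripts of splicing regulators had higher signal on the treated arrays. The list of 29 genes was written after other splicing genes had been seen among the smallest p-values, and leaves those out; 25 were measured. For both doses the median log2 difference was 0.62, with 23 of 25 genes above 0, among them the kinase Clk1 (1.15), the splicing factors Rbm39 (1.03), Luc7l3 (1.30) and Srsf2 (0.90), and the cyclin Ccnl1 (0.88), each also higher at either dose. VE50 had a median of 0.60 (23 of 25 above 0) and VE100 of 0.65 (24 of 25); the median difference between the doses was 0.10. The mean over the list lay higher on all 6 treated arrays (0.11 to 0.40) than on the 3 vehicle arrays (-0.61 to -0.17), an exact permutation p of 0.0119, the smallest that 3 against 6 arrays can give. Because splicing genes seen on these same arrays prompted the list, its p-values are no independent evidence. Camera with an estimated correlation gave p = 0.00588 for both doses, and p = 0.294 when adjusted with the 49 other lists; fry gave an adjusted p of 0.0472 and camera at the preset correlation 1.24e-13. Under 18 alternatives, the median stayed between 0.48 and 0.75 and p with an estimated correlation between 0.00283 and 0.0427; without vehicle 3 they were 0.50 and 0.0284.

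Other lists had members that went both ways for both doses. Of the unfolded protein response genes, Edem1 lay at -0.78 ± 0.21 (SE) and the kinase Eif2ak3 at 0.67 ± 0.20, and the list median was 0.02 (adjusted p = 0.934). Of genes that differ between male and female mouse liver, Fmo2 lay at 1.27 ± 0.29 and Hao2 at -0.98 ± 0.23, both female-biased, and the male-biased urinary protein gene Mup20 at 1.35 ± 0.53 (0.80 without vehicle 1; past the criterion under 12 of 19 alternatives). Respiratory chain genes had a median of 0.21, with 22 of 34 above 0 (adjusted p = 0.178). The xenobiotic receptor gene Nr1i2 lay at 0.81 ± 0.27 (0.54 without vehicle 3, no longer past the criterion), the bile acid synthesis gene Acox2 at -0.82 ± 0.25 (-0.61 without vehicle 1, no longer past it) and the endothelial gene Vwf at 0.52 ± 0.18. None passed the adjusted threshold.

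For the splicing transcripts, the trends of 2 control measures within groups are argued against as the whole cause. The fits took each trend from the deviations within groups. They cannot exclude an array-level difference between treated and vehicle arrays that departs from that trend. The mean over the list was higher on treated arrays by 0.63 ± 0.11 (SE), by 0.71 ± 0.19 with the hybridization controls as a covariate and by 0.66 ± 0.16 with the negative less the positive controls. The list median stayed at 0.65 and 0.59 with 25 of 25 genes above 0, while 62 and 24 of 126 named values no longer passed the criterion. For VE100 alone, the difference was 0.66 ± 0.13 before and 0.70 ± 0.19 with the negative less the positive controls. There the list had p = 0.0591 by camera with an estimated correlation. A part in the difference stays open for both: the intron-based negative controls, less the positive ones, were higher by 0.30 in treated arrays with vehicle 3 among them (exact permutation p = 0.0595), and the hybridization controls followed the list within groups at r = -0.25 over 9 arrays (Pearson, exact permutation p = 0.551 over 216 orders within groups; Spearman -0.27, p = 0.574; -0.58 without the 2 arrays farthest from the median). The treatment, which the design names, stays open too.

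Nr1d1 was lower on all treated arrays, and vehicle 3 alone is argued against as the source, since the difference without it was -2.09 ± 0.29 (SE). A different time of day at sampling was predicted to set clock genes of opposite phase (Cry1, Nfil3, Arntl, Npas2, Clock) above those in phase with Nr1d1 (such as Dbp, Per3, Ciart), all chosen for their phase. Their medians differed by -0.60 instead, at percentile 0.64 among 10000 random pairs of lists (SD 0.248), which goes against a shift that parts the 2 sets in the predicted way. The size of that value rests on vehicle 3, whose clock genes lay apart (circadian list median -1.59). Without vehicle 3 the difference was -0.25 at percentile 15.4, within 1 SD of 0 (0.311). It lay 0.92 below the upper bound of the random pairs that the predicted shift would have to exceed. For both doses, genes of each set went both ways. In phase, Usp2 lay at 1.32 and Bhlhe41 at -0.51, and of opposite phase, Cry1 lay at 0.81 and Arntl at -0.32. The test takes the in-phase genes as moving with Nr1d1, so it cannot decide on a shift that moves them apart. The treatment, which the design names, and such a shift stay open as hypotheses, and the labels give no sampling time.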
